A study of Mus musculus with 1615 samples.

How the data were processed

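The series holds 1615 single cells of mouse colon, each sequenced as a library of its own. They came from 11 mice, 2 female and 9 male by their labels, of 5 reporter lines, and lay on 13 plates. Each cell was sorted into a well of a plate and made into a Smart-Seq2 library, a full-length cDNA protocol without molecular identifiers. The reporter lines are named after Acta2, Cspg4, Pdgfra or Pdgfrb and a fluorescent protein, and a dual line carries the Acta2 and Cspg4 reporters together. The labels give ages of 8 to 30 weeks, while the series text speaks of males of up to 21 weeks. The tissue field says colon, while the protocol text names the heart as the dissociated organ. The gates of the sort are not given in the sources used here.

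The deposited table holds raw counts per Ensembl gene identifier and spike-in, with 1 column per cell and no normalization by the authors. The labels name bcl2fastq, Bowtie, Bowtie2, featureCounts and Subread, without versions or roles, and the builds GRCm38 and mm10. Filters on cells and any removal of duplicate reads are not given in the sources used here. The table has 46517 gene identifiers and 92 spike-ins. Reads of near-identical genes, such as Hspa1a and Hspa1b, the actins, or Y-linked genes and their X-linked paralogs, cannot be fully parted. Symbols and positions were taken from GENCODE for GRCm38. They were found for 46005 identifiers, and 512 had none and were kept under their identifier. The lowest total per cell, spike-ins included, was 50074 counts. Gene counts per cell ran from 45388 to 1046988, with a median of 194180, and 1575 to 9966 genes were detected per cell, with a median of 4657. PCR reads without molecular identifiers are not independent molecules, so all intervals and floors given here cover counting error only. Shares of cells have exact Clopper-Pearson intervals at 95%, and a count of 0 was read as a floor of 3 counts over the group.

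The gene lists, markers, contrasts, tests, thresholds, the rule for named genes and most alternatives were fixed before the data were examined. Cells with under 20000 gene counts or 1000 detected genes were to be removed, and 0 were. Counts were scaled to CPM, each cell or sum to the same total, and taken as log2(CPM + 1). Clustering used 2090 genes. These were the markers and the 2000 most variable genes among odd-numbered genes in alphabetical order that were on no test list and had counts in at least 10 cells. Cells were placed on 20 principal components and joined to 15 neighbours with scanpy 1.11.5, and Leiden clustering at resolution 1 ran through igraph 0.11.9. A cluster was given the cell type with the highest mean marker difference from all other cells, if at least 3 of its markers were detected in 25% of the cluster. Classes are therefore written as "-like". Numbers of cells with at least 2 markers of another class above that class's median were counted, and no doublet caller was run.

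Cells of a mouse are not replicates, so raw counts were summed per mouse and class, and the mouse was the replicate. Mice with at least 5 cells in both classes entered a contrast. Sums were tested with edgeR 4.0.16 under R 4.3.3, with TMM scaling, the filter filterByExpr, a robust quasi-likelihood fit and the mouse as a block. The contrast of the sexes had no block. The SE of a log2 fold change is its size over the square root of F. Each contrast left 1 residual degree of freedom, except that of lymphatic with blood endothelium, which left 4. With 1, the SE and p of a gene rest mainly on a spread pooled across genes, and little on its own variation between mice. The Benjamini-Hochberg adjustment ran over the genes not used for clustering, with a threshold of 0.05. Classes and tests still rest on the same cells, so a call is no independent evidence that a class exists. Named genes passed that threshold, had a mean of at least 50 CPM in the higher class and moved the same way in every mouse. The 10 largest log2 fold changes in each direction were taken, and up to 4 members of each list per direction by smallest p. Ribosomal, mitochondrial and predicted genes were skipped. Sex-linked genes and Acta2, Cspg4, Pdgfra and Pdgfrb were named in every case. For the sexes, up to 5 genes per direction were to be named by smallest adjusted p.

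The 14 lists cover the contractile apparatus, ion channels and calcium handling, receptors, fibrillar and elastic matrix, basement membrane, integrins and the dystrophin complex, Notch signalling, positional transcription factors, BMP, WNT and Hedgehog signalling, cell junctions, dissociation and stress, epithelial RNA, sex-linked genes and oxidative phosphorylation. A list gene that was also a marker counted as a marker. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a contrast. Camera compares a list with all other genes, while fry asks whether its members move 1 way on balance. With an estimated correlation, camera refers its statistic to the residual degrees of freedom, so that with 1 hardly any list can pass. For BMP, WNT and Hedgehog genes in visceral against vascular cells that correlation was -0.030, below the preset, yet the camera p went from 3.57e-07 to 0.107. Other lists lay far above the preset. Stress genes had 0.352 in visceral and 0.486 in pericyte against vascular cells, and contractile genes 0.583 in fibroblasts against pericytes. For such lists the camera p at the preset may be too small. Camera p-values with either correlation do not decide whether correlation within a list explains its shift. A list's median, mean and camera direction differed in sign in 6 of the 56 tests of the planned contrasts, in 9 of 14 for Des-high cells and in 7 of 14 for lymphatic cells.

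On simulated counts with the real library sizes and spread, genes changed by 3 on the log2 scale were called in 18.9% of cases for visceral against vascular smooth muscle. The share was 10.6% for pericytes against vascular smooth muscle, 49.5% for fibroblasts against visceral smooth muscle, 4.49% for fibroblasts against pericytes and 49.5% for the sexes. Changes of 1 on that scale were called in at most 2.06%. Few genes were changed, such as 93 by 1 and 95 by 3 of 14410 for visceral against vascular smooth muscle, and all other class differences were removed. The adjustment was thus stricter than in the data, where 770 genes passed, and these shares do not measure the power of the real contrasts. False calls made up 6 of 56 calls for fibroblasts against visceral smooth muscle and 9 of 58 for the sexes, above the nominal share of 0.05. They were 1 of 11 for pericytes and 1 of 19 for visceral against vascular smooth muscle, where 1 call does not tell an error rate. Each contrast had 1 simulated data set. They were 0 in the other 3 contrasts, which made at most 6 calls each.

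The alternatives were DESeq2 1.42.0, RLE size factors, no filter on low counts, at least 10 cells per mouse and class, cells of at least 100000 counts and 2000 genes, and limma on the mean log2(CPM + 1) per mouse and class. Clustering on even-numbered genes or at resolution 0.5, leaving out cells with markers of another class, no block, the dual line only and leaving out each mouse were also tried. For lists, the alternatives were an estimated correlation and fry. Chosen after seeing the data were the contrasts of lymphatic with blood endothelium and of Des-high with other visceral smooth muscle, leaving out the smaller or the larger plate of mouse 20GG95:3, and a spread shared over the sums of all classes. A planned contrast of the dual line with the PDGFRbGFP line in mural cells had no mice with enough cells. Figures were drawn with matplotlib 3.10.9.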

Results

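The data are single-cell transcriptomes of mouse colon, and the title of the series names an inventory of smooth muscle cells as its purpose. The dual line gave 1106 of the 1615 cells, from 2 females, 20GG79:1 with 359 cells and 20GG95:3 with 505, and from the male 20GG79:6 with 242. The other 8 mice were males of the lines ACTA2GFP, CSPG4dsRED, PDGFRaH2bGFP and PDGFRbGFP and gave between 5 and 199 cells each. Median gene counts per plate ran from 103035 to 438820. ERCC spike-ins, synthetic RNA added to each well, held 1.88% of all counts, and mitochondrial genes held 1.25% of gene counts.

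Clustering gave 18 clusters, and 17 of them took the names of 9 cell classes. Visceral smooth muscle-like cells were the largest class with 526 cells, followed by 357 blood endothelium-like, 217 fibroblast-like, 162 pericyte-like, 100 vascular smooth muscle-like and 79 lymphatic endothelium-like cells. Epithelium-like and immune-like cells numbered 57 each, and 42 cells were like enteric or Schwann glia. A cluster of 18 cells from the larger plate of 20GG95:3 met no naming rule and was left out of the contrasts. Acta2 and Myh11, actin and myosin of smooth muscle, stood at 5968 ± 1665 and 5084 ± 646 CPM in visceral smooth muscle-like cells (mean ± SD, n = 3 mice). In vascular smooth muscle-like cells Acta2 stood at 6709 ± 1685 CPM and Des at 2635 ± 477 CPM (n = 2 mice), while visceral cells had 960 ± 557 CPM of Des (n = 3 mice). Pln, a regulator of the calcium pump, was at 914 ± 24.6 CPM in vascular cells (n = 2 mice) and 1.36 ± 0.696 CPM in visceral cells (n = 3 mice). Pericyte-like cells had 4002 ± 541 CPM of Rgs5 and 2010 ± 275 CPM of Notch3 (n = 3 mice), and fibroblast-like cells had 3194 ± 1138 CPM of Dcn (n = 4 mice). Ano1, a chloride channel known from interstitial cells of Cajal, was at 974 ± 180 CPM in vascular (n = 2 mice), 787 ± 170 CPM in pericyte-like (n = 3 mice) and 271 ± 156 CPM in visceral smooth muscle-like cells (n = 3 mice), and no cluster took the name of that cell type. These genes were used for clustering, so their levels describe the classes and were not tested.

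**Figure D1:**
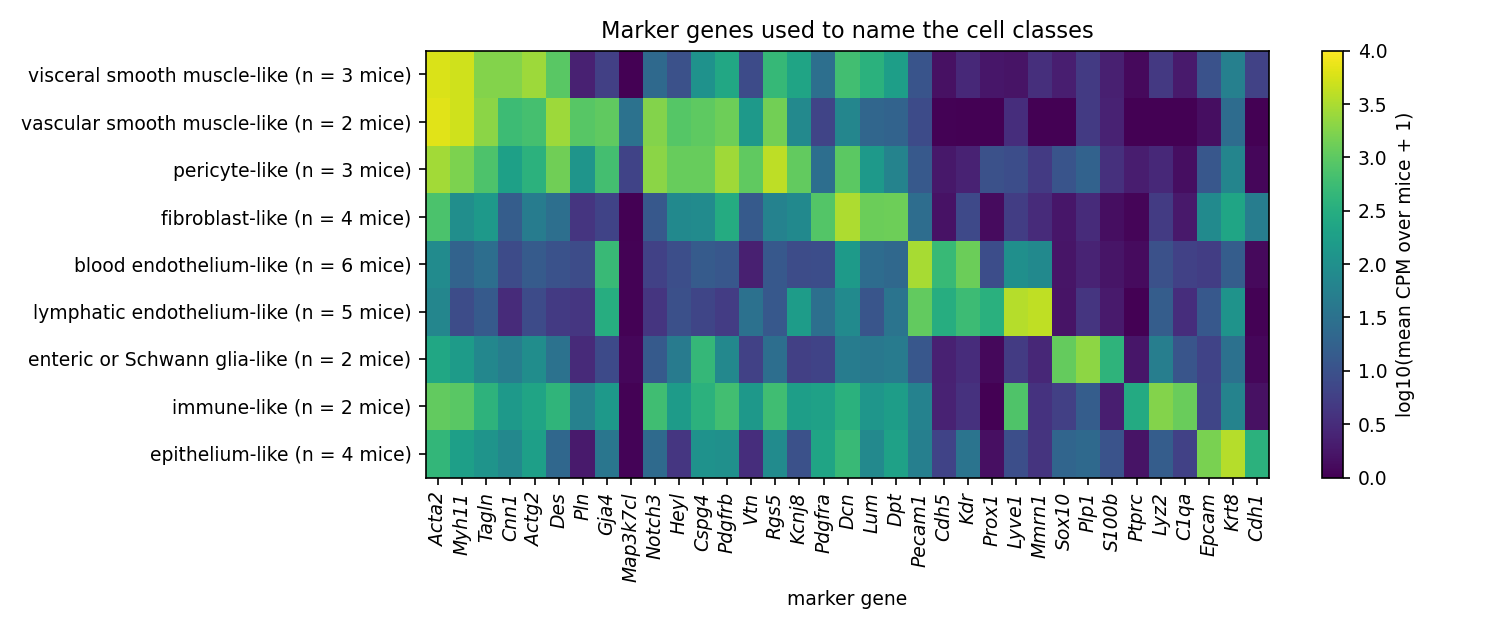
Mean CPM over mice (color, log10 of CPM + 1) of 35 marker genes (horizontal axis) in the 9 named cell classes (vertical axis, with the number of mice). Acta2 is bright in the visceral and vascular smooth muscle-like classes, at 5968 and 6709 CPM, and Rgs5 in the pericyte-like class, at 4002 CPM.

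Pericyte-like and smooth muscle-like cells were found in the dual line, and 0 in the other lines. Visceral smooth muscle-like cells made up 44.6% of the cells of 20GG79:1 (95% interval 39.3 to 49.9), 27.3% of those of 20GG79:6 (21.8 to 33.4) and 59.4% of those of 20GG95:3 (55.0 to 63.7). Blood endothelium-like cells made up 62.3% (55.2 to 69.1) of the cells of the PDGFRbGFP mouse that gave 199 cells. In the PDGFRaH2bGFP line they made up 83.5% (74.3 to 90.5) of 91 cells, with 0 fibroblast-like cells. Blood endothelium-like cells had 11.3 CPM of Pdgfrb and 7.78 CPM of Pdgfra at the mean of 6 mice, so most cells of these lines were of a class with little RNA of the gene that names the line. As the sort gates are not given in the sources used here, shares were not compared. Of all cells, 119 held markers of another class at that class's level, 50 of them visceral smooth muscle-like and 22 immune-like. Immune-like cells of 20GG79:6 had 2150 CPM of Acta2 and 1881 CPM of Myh11.

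The contrast of visceral with vascular smooth muscle-like cells asked how the muscle of the gut wall differs from that of its vessels. Visceral cells were higher in the receptor genes F2r and Bdkrb2. F2r, the thrombin receptor, stood at 1330 ± 482 against 25.2 ± 1.23 CPM (mean ± SD, n = 2 mice), a log2 fold change of 5.58 ± 0.37 (SE, adjusted p = 4.61e-18). Bdkrb2, a bradykinin receptor, rose by 7.80 ± 0.59 (adjusted p = 8.54e-16). The visceral cells were not uniform: F2r and Bdkrb2 were lower in the 104 Des-high cells described below than in the 356 others. Vascular cells were higher in P2rx1, an ATP-gated channel, which stood at 1.69 ± 1.14 CPM in visceral against 864 ± 84.6 CPM in vascular cells (n = 2 mice), a log2 fold change of -9.24 ± 0.49 (adjusted p = 3.32e-21). Kcna5, a voltage-gated potassium channel, was at 0.252 ± 0.0501 against 344 ± 11.8 CPM (n = 2 mice), a log2 fold change of -10.48 ± 0.68 (adjusted p = 9.85e-19). F2r is ENSMUSG00000048376 on chromosome 13 from 95601803 to 95618487, P2rx1 is ENSMUSG00000020787 on chromosome 11 from 72999103 to 73015200, and Kcna5 is ENSMUSG00000045534 on chromosome 6 from 126532551 to 126535412 (GRCm38).

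Of 49 receptors tested, 10 were higher in visceral cells, 9 in vascular cells and 30 did not pass (18 and 13 adjusted over the list alone). The visceral side also held Ptger1 (4.49), a prostaglandin receptor, and Lpar1 (5.22), a receptor for lysophosphatidic acid. The vascular side held S1pr3 (-8.12), Npy1r (-8.99) and Adra1a (-9.74), receptors for sphingosine phosphate, neuropeptide Y and noradrenaline. The list did not pass camera (adjusted p = 0.915), though its median log2 fold change was 2.81 and its mean 0.98. The median of all genes was 0.32. Of 41 ion channel and calcium genes, 1 rose, 7 fell and 33 did not pass (4 and 14 adjusted over the list alone). The calcium channel subunit Cacnb3 rose by 1.70, while Kcnab1 (-10.23), Cacna1g (-9.53) and the calcium pump Atp2a3 (-4.75) were higher in vascular cells. This list shifted towards vascular cells (camera adjusted p = 9.25e-05, and adjusted p = 0.468 with an estimated correlation). Other large vascular-side changes were those of Xirp1 (-11.14), Abcc8 (-11.13), Sez6l (-10.83), Scn4b (-10.39) and Grip2 (-10.23). The contractile list of 35 genes held 2 that rose, 5 that fell and 28 that did not pass (3 and 6 adjusted over the list alone, camera adjusted p = 0.123). Pdlim3 rose by 1.04, and Mylk, myosin light chain kinase, fell by 0.80.

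Fibrillar and basement membrane genes were tested as separate lists, which were not compared with each other. Of 39 fibrillar and elastic matrix genes, 22 rose, 2 fell and 15 did not pass (25 and 4 adjusted over the list alone). Col3a1, a fibrillar collagen (ENSMUSG00000026043, chromosome 1 from 45311538 to 45349706), stood at 4736 ± 1030 against 309 ± 75.5 CPM (n = 2 mice), a log2 fold change of 3.86 ± 0.24 (adjusted p = 1.65e-19). Ltbp4 (3.97), Col6a1 (3.94) and Col12a1 (6.23) rose with it, and Thbs1 fell by 2.44. The list passed camera (adjusted p = 7.43e-05, and adjusted p = 0.468 with an estimated correlation). Of 25 basement membrane genes, 7 rose, 5 fell and 13 did not pass (8 and 6 adjusted over the list alone, camera adjusted p = 0.915). Laminin subunits parted, with Lamb1 at 6.43 and Lamb2 at -2.81. In Col3a1, Lamb1 and Lamb2, Des-high cells differed from the other visceral cells in the vascular direction. Among 36 integrin and dystrophin complex genes, 6 rose, 7 fell and 23 did not pass (8 and 8 adjusted over the list alone, camera adjusted p = 0.352). Itga5 (3.93) rose, and the laminin receptors Itga7 (-3.82) and Bcam (-4.75) fell. For this list the median log2 fold change was 0.33 while camera pointed down.

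Signalling genes also differed between the classes. Of 34 BMP, WNT and Hedgehog genes, 13 rose in visceral cells, 1 fell and 20 did not pass (19 and 4 adjusted over the list alone). They included Bmp4 (5.84), Ptch1 (4.98), the receptor of Hedgehog ligands, Dkk3 (5.83) and the BMP antagonist Chrdl1 (8.68). The list passed camera at an adjusted p = 2.50e-06, and an adjusted p = 0.468 with an estimated correlation. Rspo3, an enhancer of WNT signalling, had 5397 counts in visceral and 1 in vascular cells, a ratio of 957 (95% counting interval 172 to 37800). Within visceral cells, Rspo3 was higher in Des-high cells than in the others. Of 16 Notch genes, 0 rose, 5 fell and 11 did not pass (0 and 5 adjusted over the list alone), among them Notch1 (-2.64) and the Notch targets Hey2 (-8.00) and Hes1 (-2.86). Camera gave an adjusted p = 5.69e-05, and an adjusted p = 0.468 with an estimated correlation. Of 38 positional transcription factors, 4 rose and 7 fell (6 and 9 adjusted over the list alone, camera adjusted p = 0.986). Foxf2 (8.34), Osr1 (5.64) and Tcf21 (3.66) rose, and Ebf1 (-7.39), Nr2f2 (-5.08) and Mef2c (-3.33) fell. Of 20 junction genes, 5 rose, such as Cavin2 (7.67) and Ncam1 (4.83), and 1, Mcam (-2.01), fell (7 and 3 adjusted over the list alone, camera adjusted p = 0.352).

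Of 21 dissociation and stress genes, 0 were higher in visceral and 13 in vascular cells, and 8 did not pass (0 and 14 adjusted over the list alone). Nr4a1, an immediate-early transcription factor, was at 736 ± 71.1 against 6035 ± 1725 CPM (n = 2 mice), a log2 fold change of -3.10 ± 0.22 (adjusted p = 3.45e-17). As a list, these genes had a camera adjusted p = 2.50e-06, and an adjusted p = 0.686 with an estimated correlation. Of 79 oxidative phosphorylation genes, 1 fell and 78 did not pass (0 and 1 adjusted over the list alone). The list's median was -0.19 (camera adjusted p = 0.00195, and adjusted p = 0.686 with an estimated correlation). Of 10 epithelial genes and 4 sex-linked genes tested, 0 passed in edgeR, also when adjusted over the list alone (camera adjusted p = 0.352 for both).

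Over 15136 genes, 395 rose and 375 fell at an adjusted p of at most 0.05, 770 in all, and 2210 had an unadjusted p under 0.05. The count rested on 460 visceral and 99 vascular cells of 2 female mice with 1 residual degree of freedom, and 20GG79:1 gave 9 of the vascular cells. It was 1310 with DESeq2, 1165 with limma (495 rose and 670 fell), 373 with deeper cells, 461 without the smaller plate of 20GG95:3, 335 without its larger plate, 214 without the block and 18 with a spread shared over all classes. With that shared spread, 76 of 87 values for named genes of this contrast lost the call.

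**Figure D2:**
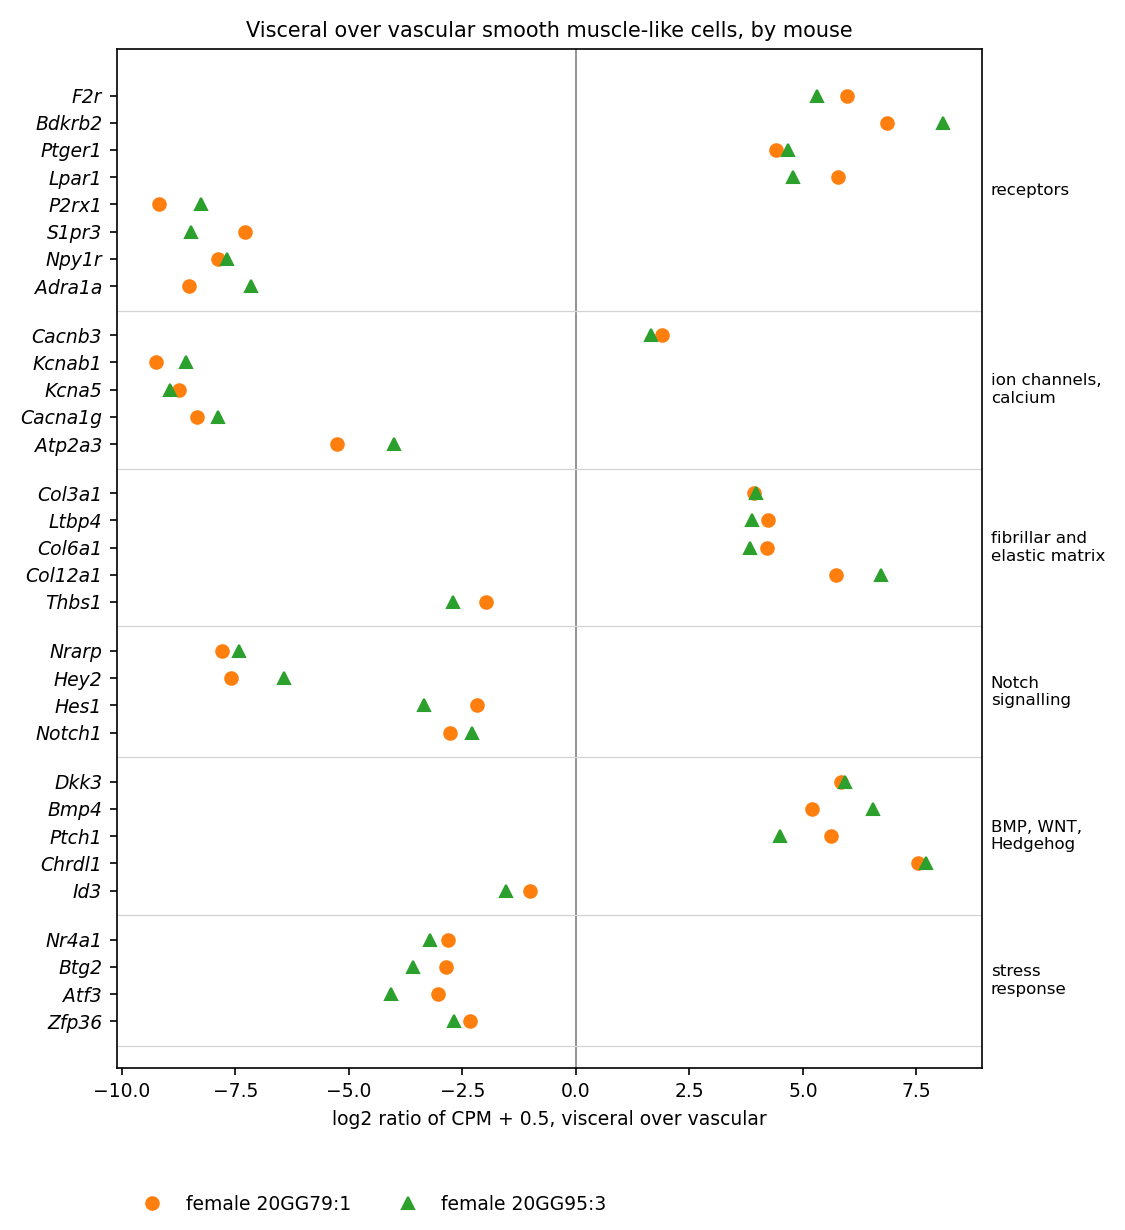
Log2 ratio of CPM + 0.5 (horizontal axis) of visceral over vascular smooth muscle-like cells for named genes of 6 lists (vertical axis), each point 1 of 2 female mice. Receptors lie on both sides of 0, with fitted log2 fold changes of 5.58 for F2r and -9.24 for P2rx1, and the 4 stress genes shown lie below 0.

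Pericyte-like cells were compared with vascular smooth muscle-like cells, the other mural class. Smtn was lower in pericytes and Agtr1a higher. Smtn, the smooth muscle protein smoothelin (ENSMUSG00000020439, chromosome 11 from 3517523 to 3540612), stood at 184 ± 76.8 against 1482 ± 162 CPM (mean ± SD, n = 2 mice), a log2 fold change of -3.29 ± 0.37 (SE, adjusted p = 3.43e-05). Agtr1a, the angiotensin receptor (ENSMUSG00000049115, chromosome 13 from 30336441 to 30382867), stood at 295 ± 7.38 against 2.80 ± 3.04 CPM (n = 2 mice), a log2 fold change of 7.13 ± 0.89 (adjusted p = 8.61e-05). P2rx1 was lower here too, by -7.53 ± 0.55 (adjusted p = 3.94e-07).

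Of 34 contractile genes, 0 rose, 10 fell and 24 did not pass (1 and 19 adjusted over the list alone). They included Myocd (-2.87), a coactivator of smooth muscle genes, Mylk (-1.89) and Flna (-1.66). In camera the list had an adjusted p = 1.10e-06, and an adjusted p = 0.609 with an estimated correlation. Of 38 ion channel and calcium genes, 5 fell and 33 did not pass (0 and 10 adjusted over the list alone), such as the potassium channel genes Kcnh2 (-5.33) and Kcnab1 (-5.72). This list shifted as well (camera adjusted p = 0.000216, and adjusted p = 0.609 with an estimated correlation). Among 40 receptors, Agtr1a rose and 5 fell, S1pr3 (-2.81) and Npy1r (-3.88) among them (6 and 6 adjusted over the list alone, camera adjusted p = 0.552). Of 38 fibrillar and elastic matrix genes, 12 rose, 2 fell and 24 did not pass (19 and 3 adjusted over the list alone). Col3a1 rose by 3.37 and Col6a1 by 3.39 (camera adjusted p = 0.000309, and adjusted p = 0.609 with an estimated correlation). Of 26 basement membrane genes, 6 rose and 1 fell (9 and 3 adjusted over the list alone, camera adjusted p = 0.198), with Lamb1 at 5.99 and Lamc3 at 5.11.

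Of 29 BMP, WNT and Hedgehog genes, 4 rose, 0 fell and 25 did not pass (8 and 2 adjusted over the list alone), among them Chrdl1 (9.81) and Bmp4 (3.75). The list passed camera at an adjusted p = 1.44e-05, and an adjusted p = 0.609 with an estimated correlation. Of 33 integrin and dystrophin complex genes, 3 fell, among them Bcam (-1.67), and 30 did not pass (0 and 9 adjusted over the list alone). That list gave a camera adjusted p = 0.00413, and an adjusted p = 0.609 with an estimated correlation. The Notch ligand Dll4 rose by 6.41, alone among 15 Notch genes (1 and 0 adjusted over the list alone, camera adjusted p = 0.993). Sdc1 (10.45), Colec11 (8.86), Slco2b1 (6.85) and Ccl11 (6.79) also rose, and Sez6l (-9.64) and Abcc8 (-7.46) fell. Marcks had 1709 counts in pericytes and 1 in vascular cells, a ratio of 1430 (95% counting interval 256 to 56500).

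Of 21 dissociation and stress genes, 0 were higher in pericytes, 12 were higher in vascular cells and 9 did not pass (0 and 17 adjusted over the list alone), with Nr4a1 at -3.31. Camera gave an adjusted p = 3.10e-08, and an adjusted p = 0.609 with an estimated correlation. For 78 oxidative phosphorylation genes the median was -0.35, with 1 that fell (0 and 0 adjusted over the list alone, camera adjusted p = 0.00392, and adjusted p = 0.724 with an estimated correlation). Over 13160 genes, 84 rose and 126 fell, 210 in all, and 1365 had an unadjusted p under 0.05. The fit had 1 residual degree of freedom and the same 9 vascular cells of 20GG79:1, beside 149 pericyte-like cells. The count was 751 with DESeq2 (405 rose and 346 fell), 991 with limma, 348 with RLE factors, 126 at resolution 0.5, 116 without cells holding markers of another class, 106 without the smaller plate of 20GG95:3, 123 without its larger plate, 36 with deeper cells, 21 without the block (12 rose and 9 fell) and 1 with a spread shared over all classes.

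Fibroblast-like and visceral smooth muscle-like cells were compared in the female 20GG79:1 and the male 20GG79:6. Fibroblasts were lower in Lmod1 and other contractile genes and higher in Gja1. Lmod1, leiomodin, a nucleator of actin filaments (ENSMUSG00000048096, chromosome 1 from 135324807 to 135368065), stood at 10.3 ± 3.68 against 401 ± 30.5 CPM (mean ± SD, n = 2 mice), a log2 fold change of -5.33 ± 0.38 (SE, adjusted p = 0.00427). Gja1, the gap junction protein connexin (ENSMUSG00000050953, chromosome 10 from 56377330 to 56402513), stood at 537 ± 99.0 against 8.46 ± 3.66 CPM (n = 2 mice), a log2 fold change of 6.04 ± 0.34 (adjusted p = 0.00427). Hhip, an inhibitor of Hedgehog ligands, was at 56.3 ± 36.0 against 2242 ± 85.9 CPM (n = 2 mice), a log2 fold change of -5.48 ± 0.36 (adjusted p = 0.00427).

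Of 35 contractile genes, 0 rose, 18 fell and 17 did not pass (2 and 23 adjusted over the list alone), among them Flna (-2.48), Myocd (-3.36) and Myl9 (-2.15). As a list, these genes had a camera adjusted p = 1.97e-09, and an adjusted p = 0.565 with an estimated correlation. Of 40 ion channel and calcium genes, 1 rose, 8 fell and 31 did not pass (5 and 15 adjusted over the list alone). Cacna1g rose by 6.02, while Cacna1h (-3.83), Kcnmb1 (-3.13) and Trpc6 (-5.86) fell. This list passed camera too (adjusted p = 0.000397, and adjusted p = 0.565 with an estimated correlation). Among 48 receptors, Agtr1a (4.40) rose and 6 fell, among them Bdkrb2 (-3.09), F2r (-1.48) and Tacr2 (-7.07), a tachykinin receptor (4 and 7 adjusted over the list alone, camera adjusted p = 0.387). Of 39 fibrillar and elastic matrix genes, 7 rose, 0 fell and 32 did not pass (23 and 3 adjusted over the list alone). Fbln1 rose by 2.80, Tnc by 2.41 and Col1a2 by 1.19 (camera adjusted p = 7.60e-05, and adjusted p = 0.565 with an estimated correlation).

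Of 29 basement membrane genes, 3 rose and 2 fell (10 and 3 adjusted over the list alone, camera adjusted p = 0.296), with Col4a5 at 3.31, Col4a6 at 5.02 and Tinagl1 at -5.55. Of 35 integrin and dystrophin complex genes, 8 fell, among them Dtna (-6.87) and Dmd (-2.65), and 27 did not pass (1 and 13 adjusted over the list alone). That list gave a camera adjusted p = 8.09e-05, and an adjusted p = 0.565 with an estimated correlation. Of 20 junction genes, 2 rose, 4 fell and 14 did not pass (3 and 11 adjusted over the list alone), with Cdh11 at 2.63 and Mcam at -3.98. In camera the list had an adjusted p = 0.0438, and an adjusted p = 0.565 with an estimated correlation. Of 36 BMP, WNT and Hedgehog genes, 4 rose and 3 fell (11 and 4 adjusted over the list alone, camera adjusted p = 0.290). Bmp3 (6.07), Wif1 (4.78) and Wnt5a (2.27) rose, and Chrdl1 (-5.49) fell with Hhip. The Notch ligand Dll1 rose by 5.05, and 0 of 34 positional transcription factors passed in edgeR, also when adjusted over the list alone (camera adjusted p = 0.987).

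Hspb1 (-2.52) and Hspa1a (-1.59), both heat-shock genes, fell in fibroblasts, and the other 19 dissociation and stress genes did not pass (0 and 10 adjusted over the list alone). The list passed camera at an adjusted p = 0.000241, and an adjusted p = 0.603 with an estimated correlation. Of 79 oxidative phosphorylation genes, 0 passed in edgeR, and the median was -0.29 (camera adjusted p = 0.0191, and adjusted p = 0.565 with an estimated correlation). Over 15981 genes, 128 rose and 160 fell, 288 in all, and 1867 had an unadjusted p under 0.05. The count came from 196 fibroblast-like and 226 visceral cells with 1 residual degree of freedom. False calls exceeded the nominal share in 1 simulated data set, at 6 of 56 calls. The balance turned to more genes rising than falling with DESeq2 (759 and 594 of 1353), limma (1056 and 576 of 1632), without the filter on low counts (362 and 323) and without cells holding markers of another class (267 and 245 of 512). The count was 165 with deeper cells, 191 without the block, 84 after clustering on even-numbered genes against 227 over the same genes, and 0 with a spread shared over all classes, where 876 genes had an unadjusted p under 0.05.

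**Figure D3:**
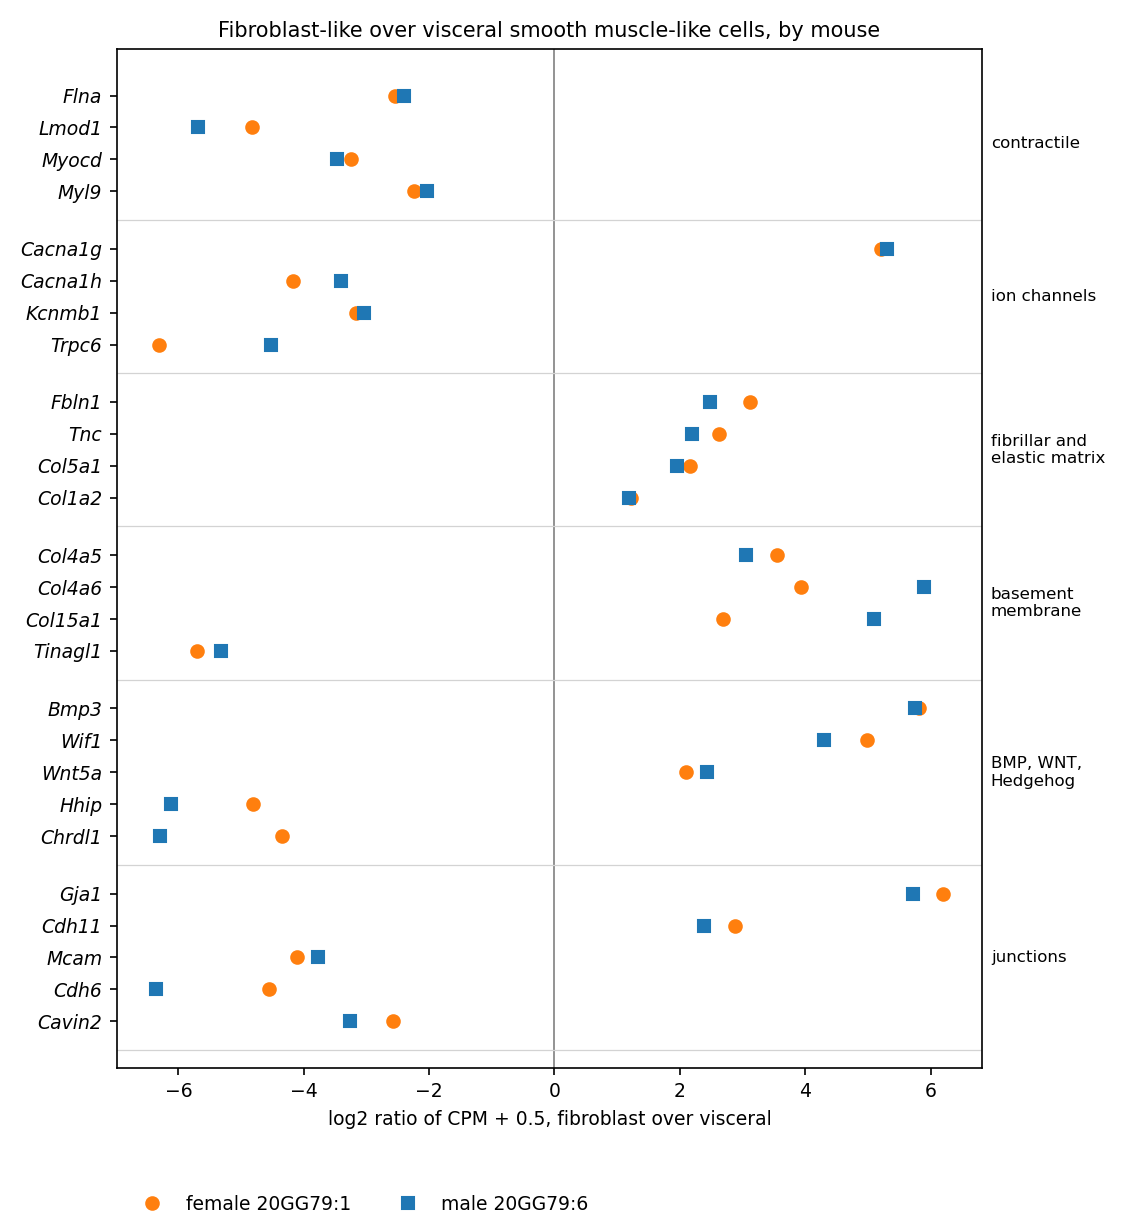
Log2 ratio of CPM + 0.5 (horizontal axis) of fibroblast-like over visceral smooth muscle-like cells for named genes of 6 lists (vertical axis), each point 1 of 2 mice, female or male. The 4 contractile genes shown lie below 0 in both mice, with fitted log2 fold changes from -2.15 for Myl9 to -5.33 for Lmod1.

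Fibroblast-like and pericyte-like cells, both of which express Pdgfrb, were compared in the same 2 mice. Fibronectin rose in fibroblasts, while Lamc3 and Bcam fell. Fn1 (ENSMUSG00000026193, chromosome 1 from 71585520 to 71653200) stood at 3140 ± 626 against 318 ± 26.9 CPM (mean ± SD, n = 2 mice), a log2 fold change of 3.20 ± 0.27 (SE, adjusted p = 2.19e-09). Lamc3, a laminin chain (ENSMUSG00000026840, chromosome 2 from 31887291 to 31946539), was at 2.17 ± 1.25 against 767 ± 319 CPM (n = 2 mice), a log2 fold change of -8.61 ± 0.61 (adjusted p = 8.24e-11). Bcam, a laminin receptor, changed by -6.36 ± 0.46 (adjusted p = 9.43e-11).

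Of 39 fibrillar and elastic matrix genes, 21 rose, 0 fell and 18 did not pass (25 and 0 adjusted over the list alone), among them Col1a2 (1.70) and Loxl1 (3.73), an enzyme that crosslinks elastic fibres. Camera gave an adjusted p = 0.000127, and an adjusted p = 0.575 with an estimated correlation. Of 15 Notch genes, 4 fell, 0 rose and 11 did not pass (1 and 5 adjusted over the list alone), including Notch1 (-4.89) and Jag1 (-4.88). The list had a camera adjusted p = 0.000663, or adjusted p = 0.575 with an estimated correlation, and a fry adjusted p = 0.0225. Of 36 ion channel and calcium genes, 1 rose, 4 fell and 31 did not pass (2 and 10 adjusted over the list alone), with Kcnn3 at 4.84 and Kcne4 at -3.65. This list, too, had a camera adjusted p = 1.45e-05, or adjusted p = 0.575 with an estimated correlation, and a fry adjusted p = 0.0225. Of 35 contractile genes, 7 fell and 28 did not pass (1 and 17 adjusted over the list alone), with Myl9 at -1.57 (camera adjusted p = 2.03e-05, and adjusted p = 0.693 with an estimated correlation).

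Of 33 BMP, WNT and Hedgehog genes, 8 rose, 0 fell and 25 did not pass (10 and 1 adjusted over the list alone), with Bmp3 at 7.03, Wif1 at 6.76 and Wnt5a at 3.64. The list passed camera at an adjusted p = 0.0184, and an adjusted p = 0.575 with an estimated correlation. Of 34 integrin and dystrophin complex genes, 4 fell and 30 did not pass (1 and 8 adjusted over the list alone), Itga7 (-7.20) and Bcam among them (camera adjusted p = 0.00303, and adjusted p = 0.616 with an estimated correlation). Among 46 receptors 4 rose, such as Lpar1 (3.88), and 4 fell, such as Gucy1a1 (-2.13), a subunit of the nitric oxide receptor (7 and 6 adjusted over the list alone, camera adjusted p = 0.927). The receptor list had a median of 0.37 while camera pointed down. Of 28 basement membrane genes, 3 rose and 3 fell (9 and 7 adjusted over the list alone, camera adjusted p = 0.611). Col15a1 rose by 4.51 and Tinagl1 changed by -6.56. Of 20 junction genes, 2 rose, Gja1 (5.66) and Cdh11 (3.61), and Mcam (-5.49) and Cdh2 (-7.62) fell (5 and 2 adjusted over the list alone, camera adjusted p = 0.611). Ebf1 (-5.08) and Mef2c (-4.86) were among 4 of 29 positional transcription factors that fell (1 and 5 adjusted over the list alone, camera adjusted p = 0.213). The olfactory receptor Olfr78 changed by -7.90.

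Atf3 (-4.23), Nr4a1 (-2.17) and Fos (-1.17) fell in fibroblasts, and the other 18 dissociation and stress genes did not pass (0 and 5 adjusted over the list alone). Camera gave an adjusted p = 0.000698, and an adjusted p = 0.616 with an estimated correlation. Among 13 epithelial genes 0 passed in edgeR, while the list shifted down in camera (adjusted p = 0.0352, and adjusted p = 0.715 with an estimated correlation). Oxidative phosphorylation had 0 of 79 genes past the threshold and a median of -0.17 (camera adjusted p = 0.0352, and adjusted p = 0.575 with an estimated correlation). Over 14357 genes, 123 rose and 114 fell, 237 in all, and 1448 had an unadjusted p under 0.05. The median of all genes was 0.27 with TMM, 0.13 with RLE factors and -0.17 with DESeq2, which tested more genes, and relative to that with TMM the matrix list had a median of 1.27 and the contractile list one of -1.25. The count came from 196 fibroblast-like and 67 pericyte-like cells, 13 of the latter from the male, and was 846 with DESeq2, 1330 with limma (1040 rose and 290 fell), 152 with RLE factors (67 and 85) and 66 with deeper cells (28 and 38). It was 0 in edgeR without the block, where 1484 genes had an unadjusted p under 0.05, 0 after clustering on even-numbered genes against 187 over the same genes (1442 unadjusted), and 1 with a spread shared over all classes.

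The genes that name the reporters were markers and were not tested. Acta2 stood at 1305 ± 182 CPM in fibroblast-like and 5012 ± 264 CPM in visceral smooth muscle-like cells of the same mice (mean ± SD, n = 2 mice). Cspg4 stood at 150 ± 40.9 CPM in fibroblast-like and 1267 ± 38.3 CPM in pericyte-like cells (n = 2 mice). Pdgfra was at 1263 ± 332 CPM in fibroblast-like and 42.3 ± 20.6 CPM in visceral cells (n = 2 mice). Pdgfrb reached 2577 ± 257 CPM in pericyte-like and 435 ± 0.974 CPM in fibroblast-like cells (n = 2 mice).

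**Figure D4:**
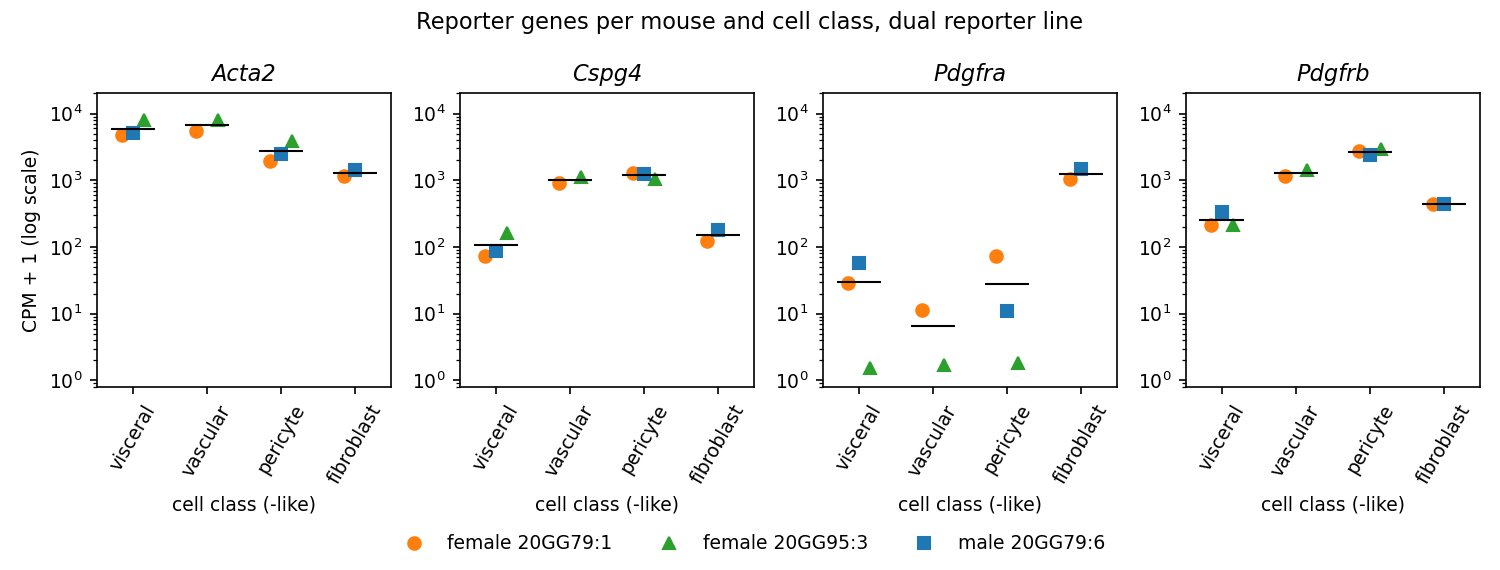
CPM + 1 on a log scale (vertical axis) of Acta2, Cspg4, Pdgfra and Pdgfrb in 4 cell classes (horizontal axis) of the dual reporter line, with 1 point per mouse and class of at least 5 cells that entered a contrast and the mean as a line. Fibroblast-like cells lie at 1176 and 1434 CPM of Acta2 in 20GG79:1 and 20GG79:6.

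The series text speaks of males, while the labels name both sexes. Xist and the Y-linked genes matched the labelled sex in 11 of 11 mice. The PDGFRbGFP male that gave 199 cells had 351 counts of Xist, or 4.45 CPM, beside 77.3 CPM of Ddx3y, and the females 20GG79:1 and 20GG95:3 had 467 and 578 CPM of Xist. Xist (ENSMUSG00000086503, chromosome X from 103460366 to 103483254), the RNA that silences an X chromosome, was the gene called between female and male visceral smooth muscle-like cells. It stood at 484 ± 92.2 CPM in 2 females and 0.432 CPM in 1 male, a log2 fold change of 10.19. With 1 male in this fit, only effect sizes are given for single genes. Tsix, the antisense RNA of Xist, was at least 525-fold higher in females, and the libraries do not mark the strand, so its reads cannot be parted from those of Xist where both overlap. Eif2s3y had 825 counts in the male and 2 in the females, a ratio of 2530 (95% counting interval 699 to 20900). Ddx3y gave a log2 fold change of -8.07, Uty -4.13 and Kdm5d -2.26.

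Of 18607 genes 1 was called between the sexes, and 2806 had an unadjusted p under 0.05. With 1 male, the spread comes from the 2 females alone and sex, mouse and plate cannot be told apart, and visceral clusters also split by mouse. The count was 1665 with DESeq2, 11 with limma, 250 without the filter on low counts, 226 without the larger plate of 20GG95:3, 16 after clustering on even-numbered genes, 2 with RLE factors or at resolution 0.5, and 0 in edgeR without the smaller plate of 20GG95:3 (1943 unadjusted) or without cells holding markers of another class (3161 unadjusted).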

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

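The tests of visceral RNA, with its comparison of Acta2 over Myh11, of pericyte RNA and of a plate or mouse batch were chosen after their results had been seen, as was reading the slope of Acta2 beside those of genes at few counts.

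Among 55 genes named between lymphatic and blood endothelium-like cells over 5 mice, 2 had a mouse far from the others, where chance alone gives about 1 in 20. Sh3gl3 had a log2 ratio of 2.111 in 20GG79:6, against 6.93 to 7.57 in the other mice, and Tnc had 0.5297 in 18CB39:3, against 4.81 to 6.07. The lymphatic sum held 5 cells in 20GG79:6 and 9 in 18CB39:3. A signal outside the comparisons was that of the ERCC spike-ins, at 1.881% of all counts. Gene identifiers without a symbol held 0.1894% of gene counts.

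Acta2 in fibroblast-like cells of 20GG79:1 and 20GG79:6 stood at 1305 CPM, against 5012 CPM in their visceral smooth muscle-like cells, and at 46.3 to 242.4 CPM in fibroblast-like cells of 4 mice without smooth muscle-like cells (4 or 5 cells each, of other lines and plates). Against pericyte RNA as the source, 8 pericyte genes stood at a median of 0.03924 of the share that Acta2 had, in the mouse with the higher value. RNA of visceral smooth muscle cannot be told apart from expression by the fibroblasts: the corresponding median was 0.1393 in 20GG79:1 and 0.0889 in 20GG79:6, but a ceiling on Acta2 in visceral cells stays open and would raise it. Acta2 over Myh11 was 9.64 in fibroblast-like against 1.89 in endothelium-like and glia-like cells in the male, and 5.77 against 5.14, from 4 such cells, in the female. The pooled value of the male leans on glia-like cells, with 295.9 CPM of Myh11 summed but a median of 60.3. Its lymphatic endothelium-like cells had 166 CPM of Acta2 and 28.2 CPM of Myh11. The background thus has no single ratio, and this comparison does not decide. A minority of cells with much Acta2 stays open too, as the median over fibroblast-like cells was 44.1% of the mean in the female and 73.9% in the male, and no biological explanation was tested.

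Immediate-early genes were higher in vascular than in visceral smooth muscle-like cells. A plate or mouse batch is argued against, since within 3 single plates the median log2 ratio of visceral to vascular over 21 stress genes was -1.033, on the plate with 9 vascular cells, -1.60 and -1.33. A stress response that takes heat-shock genes along cannot be told apart from activity in the tissue: 6 heat-shock genes had a median of -0.2597 with 1 called, and 15 other members one of -1.87 with 12 called, while for pericytes against vascular cells the same 6 genes had a median of -1.30 with 0 called in edgeR. A faster or longer response of vascular cells to dissociation may give the same picture, and no biological explanation was tested.

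Counts of single genes in single cells had a low ceiling. The median of the highest gene count per cell was 2772 in cells below 100000 counts and 3044 in cells above 400000, and the highest count of all was 8154, of Muc2. Saturation with depth fits, as the top spike-in held a smaller share in the deeper of 2 equal sets of cells in 10 of 10 plates, 17.7% against 20.8% at the median. In visceral smooth muscle-like cells of 20GG79:1 the slope of log2 Acta2 counts on log2 depth was 0.4871, against 0.709 to 0.906 for Myl9, Actg2, Myh11 and Pdgfrb. In those of 20GG79:6 it was 0.464, against 0.549 for Myl9 to 0.908 for Myh11. The threshold written beforehand for a ceiling was met in both mice. In 20GG79:6, however, genes at few counts in other classes had slopes as low, such as Myh11 in fibroblast-like cells (0.432), so that mouse does not decide. Fold changes of Acta2 between smooth muscle and other cells may therefore be too small, which cannot be told from these slopes. The same may hold for other genes at high counts, as the highest count per cell, of any gene, hardly grew with depth. The step that sets the ceiling is not given in the sources used here.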

How the results depend on the processing

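Leaving out a plate, the spread shared over all classes, and every alternative for the contrasts of lymphatic with blood endothelium and of Des-high with other visceral cells were chosen after seeing the data. Of the values compared for named genes, 3578 stayed the same, 1057 lost the call, 15 gained it, 48 untested values moved and 0 tested values reversed. A tested value stayed the same if it kept direction and side of the threshold. An untested value did if it moved by no more than the SD between mice, whatever its sign. Of those that stayed, 275 with the dual line alone were fixed in advance, as these fits hold the same data. So were 68, 59 and 10 with at least 10 cells, for fibroblasts against pericytes, fibroblasts against visceral cells and the sexes. Calls were lost most often with the shared spread (256 of 330) and without the block (196 of 369), against 62 of 353 with DESeq2 and 18 of 378 with limma. The shared spread took 76 of 87 for visceral and 57 of 61 for pericytes against vascular cells. It took 55 of 59 for fibroblasts against visceral cells, 63 of 68 against pericytes, and 5 of 55 for lymphatic cells. Sex-linked genes between classes changed sign in 41 of 340 values and reporter genes in 19 of 271. No sex-linked gene was called there, while reporter genes, as markers, could not be called in any setting. Entering the sex-linked genes as a count was decided after this was seen.

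Counts of called genes follow in the order visceral against vascular, pericytes against vascular, fibroblasts against visceral, fibroblasts against pericytes, and the sexes, with main counts of 770, 210, 288, 237 and 1. DESeq2 gave 1310, 751, 1353, 846 and 1665, and limma 1165, 991, 1632, 1330 and 11. Without the block the 4 class contrasts gave 214, 21, 191 and 0, and with the shared spread 18, 1, 0 and 1. Deeper cells gave 373, 36, 165 and 66 in the class contrasts and 1 for the sexes. RLE factors gave 348 for pericytes against vascular cells, 152 for fibroblasts against pericytes and 2 for the sexes. Without the filter on low counts, fibroblasts against visceral cells gave about 6.9e+02 (362 higher and 323 lower) and the sexes 250. Clustering on even-numbered genes gave 84 for fibroblasts against visceral cells, 0 against pericytes and 16 for the sexes, and resolution 0.5 gave 126 for pericytes against vascular cells and 2 for the sexes. Leaving out cells with markers of another class gave 116, 512 and 0 for pericytes against vascular cells, fibroblasts against visceral cells and the sexes. Without the smaller plate of 20GG95:3 visceral and pericyte against vascular cells gave 461 and 106 and the sexes 0, and without its larger plate 335, 123 and 226. The zeros are from edgeR, where 876, 1484, 1442, 3161 and 1943 genes had an unadjusted p under 0.05 (shared spread, no block, even-numbered genes, without other-class markers, without the smaller plate). The cause was not tested, except that deeper cells and left-out plates leave fewer cells.

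Des-high against other visceral cells gave 58 called genes, and 345 with DESeq2, 146 with limma, 11 with RLE factors and 1 without the block. Lymphatic against blood endothelium gave 379, and 1883 with DESeq2, 789 with limma, 761 with the shared spread, 639 without the filter, 203 with deeper cells, 193 with at least 10 cells, and 149 to 267 on leaving out each mouse, with 149 without 19CB27:3, 197 without the PDGFRbGFP male, 221 without 20GG79:6, 248 without 18CB39:3 and 267 without 18CB109:10. The share of genes higher in the first class moved from 51.3% to 64.7% with DESeq2 for visceral against vascular cells and from 40% to 12.2% with limma for pericytes. The median of all genes went from -0.71 to -0.46 with RLE factors, -0.10 with limma and 0.24 with DESeq2 for Des-high cells, and from -0.70 to -0.41, 0.27 and 0.79 for lymphatic cells. It changed sign with DESeq2 for visceral against vascular cells, fibroblasts against pericytes and the sexes too (-0.087, -0.17 and -0.025), and with limma for visceral and pericyte against vascular cells and the sexes (-0.11, -0.27 and -0.25), where these alternatives test other sets of genes.

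Of 56 list tests in the class contrasts, 29 passed camera (6, 7, 7 and 9), 0 with an estimated correlation in any contrast and 2 with fry, both for fibroblasts against pericytes (0, 0, 0 and 2). As 1 residual degree of freedom leaves hardly any list able to pass with an estimated correlation, that 0 does not decide. In lymphatic against blood endothelium 6 lists passed fry and 3 camera, and of those passing fry, 2 pointed the other way from camera, integrins at an adjusted p = 0.02878 and BMP, WNT and Hedgehog signalling at 0.003744, where camera compares with a median of all genes below 0. Class shares stayed within their intervals in 24 of 30 values, and immune-like cells went from 3.53% to 1.86% on even-numbered genes. Sex labels matched in 11 of 11 mice with either choice of cells, a void alternative because 0 cells were removed. The dual line alone changed no class contrast, as all their cells are of that line, and at least 10 cells left the fibroblast contrasts as they were.

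Not run were at least 10 cells for the contrasts with vascular cells and leaving out a mouse in all contrasts but the lymphatic one, for lack of residual degrees of freedom or of a male. For Des-high cells, at least 10 cells, deeper cells, even-numbered genes and leaving out cells with markers of another class were not run for the same reason. The dual line could not be compared with the PDGFRbGFP line. On simulated counts with the real depth, spread and number of mice, changes of 3 on the log2 scale were found in 2.08% of cases for Des-high and 6.25% for lymphatic cells, and depth was not varied alone. As few genes were changed there, these shares do not measure the power on the real data.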

Other observations

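Both contrasts below and their tests were chosen after seeing the data, except for the prediction on splits, which was written before they were run.

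Reln was higher and Bcam lower in lymphatic than in blood endothelium-like cells. Reln, the secreted protein reelin (ENSMUSG00000042453, chromosome 5 from 21884454 to 22344702), stood at 1150 ± 272 against 3.14 ± 1.69 CPM (mean ± SD, n = 5 mice), a log2 fold change of 8.71 ± 0.53 (SE, adjusted p = 7.23e-07, higher in 5 of 5 mice). Bcam, a laminin receptor, stood at 20.3 ± 11.7 against 1356 ± 326 CPM (n = 5 mice), a log2 fold change of -6.32 ± 0.38 (adjusted p = 7.23e-07). Of 37 fibrillar and elastic matrix genes, 3 rose, Prelp (5.88), Tnxb (6.45) and Tnc (4.98), 1 fell and 33 did not pass (8 and 2 adjusted over the list alone). The list passed camera (adjusted p = 0.000154, and adjusted p = 0.649 with an estimated correlation). Of 23 basement membrane genes, Col18a1 (5.07) rose and 7 fell, among them Sparc (-3.73) and Col15a1 (-6.58) (3 and 11 adjusted over the list alone). Of 21 dissociation and stress genes 6 fell, such as Ier3 (-4.07) and Fos (-2.21) (0 and 12 adjusted over the list alone, camera adjusted p = 0.00337, and adjusted p = 0.649 with an estimated correlation). Of 34 contractile genes, Cald1 (2.56) rose and 33 did not pass (1 and 0 adjusted over the list alone, camera adjusted p = 0.0253, and adjusted p = 0.649 with an estimated correlation). The nitric oxide receptor genes Gucy1a1 (3.79) and Gucy1b1 (5.48) rose, and the Notch ligand Jag2 (-7.62) fell. The median of all genes was -0.70, and relative to it the matrix list had a median of 1.17 and the stress list one of -1.215. The contractile list had a median of -0.07 while camera pointed up.

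Over 13698 genes, 142 rose and 237 fell, 379 in all, from 79 lymphatic and 289 blood endothelium-like cells. All mice in this fit were males, of the lines PDGFRbGFP, PDGFRaH2bGFP, CSPG4dsRED and the dual line. Mice 18CB109:10 and 20GG79:6 gave only 5 lymphatic cells each and 18CB39:3 gave 9. The real split of the 10 sums called 379 genes and the highest of the others 1, so that 1 of 100 splits, the real one, called as many. This does not decide on chance: 16 of the splits part every mouse as the real one does, too few for a share under 0.05, and the classes were made from the same cells. More genes rose than fell with limma, 518 and 271. The count was 149 without 19CB27:3, 197 without the PDGFRbGFP male, 221 without 20GG79:6 and 248 without 18CB39:3.

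Des-high cells, a visceral smooth muscle-like cluster, differed from the other visceral cells of 20GG79:1 and 20GG95:3. The BMP antagonist Grem1 rose by 3.997 ± 0.75 (SE, n = 2 mice, adjusted p = 7.08e-05). F2r and Hhip were lower, at log2 fold changes of -5.12 ± 0.56 (n = 2 mice, adjusted p = 6.27e-16) and -2.95 ± 0.42 (adjusted p = 7.87e-09). Of 35 BMP, WNT and Hedgehog genes, 4 rose, 1 fell and 30 did not pass (6 and 1 adjusted over the list alone, camera adjusted p = 0.00813, and adjusted p = 0.792 with an estimated correlation). Of 34 contractile genes, Pde5a (2.40) rose and 33 did not pass (1 and 0 adjusted over the list alone, camera adjusted p = 0.00187, and adjusted p = 0.792 with an estimated correlation). The oxidative phosphorylation list had a median of 0.12 (camera adjusted p = 0.00133, and adjusted p = 0.792 with an estimated correlation). The BMP, WNT and Hedgehog list had a median of 0.17 and the contractile list one of 0.24. Camera set these lists against all other genes, whose median was low: that of all genes was -0.71. It was -0.10 with limma and 0.24 with DESeq2, which test other sets of genes. With fry, 0 of 14 lists passed. Of 40 receptors, 4 rose, such as Ptger1 (2.98) and Tacr2 (4.24), 4 fell, such as F2r and Bdkrb2 (-4.48), and 32 did not pass (6 and 4 adjusted over the list alone, camera adjusted p = 0.918). Of 38 fibrillar and elastic matrix genes, Fmod (7.13) rose, 5 fell, such as Col3a1 (-1.55), and 32 did not pass (4 and 10 adjusted over the list alone, camera adjusted p = 0.318). Of 26 basement membrane genes, Npnt (6.65), nephronectin, an integrin ligand, and Lamb2 (2.63) rose, Lamb1 (-2.87) fell and 23 did not pass (2 and 2 adjusted over the list alone, camera adjusted p = 0.918). Rspo3 rose by 6.05. Of 14248 genes, 32 rose and 26 fell, 58 in all, with 104 Des-high cells, 5 of them from 20GG79:1, against 356 others. The count was 345 with DESeq2, where 98 rose and 247 fell, 146 with limma, with 73 each way, 11 with RLE factors, with 9 and 2, and 1 without the block.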
